A study of Mus musculus with 2 samples.

How the data were processed

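H3K36me3 ChIP-seq was carried out on facial prominences of mouse embryos of strain B6NCrl at embryonic day 10.5, in 2 biological replicates made from separate embryo pools per the labels, with 69 embryos in replicate 1 and 51 in replicate 2 and a fragment size range of 300 to 500 bp. The deposited data used here were 4 narrowPeak lists on build mm10: a list per replicate, a pooled list derived from both libraries and a list of replicated peaks. Per the deposited file records, replicate 1's list was made from its own alignments and 2 further files, replicate 2's from its own alignments and 1 of those same 2 files, so the lists share an input and are not fully independent; the role of these further files, the aligner, the peak caller and the rule for keeping replicated peaks are not given in the sources used here. The authors deposited for each peak an enrichment value, a linear ratio without a stated reference, and the −log10 of a p and of a q value. The smallest −log10 p-value in the deposited lists was just above 2 in each, so peaks were kept by the authors down to about p = 0.01, and 89.4% of replicate 1's and 93.0% of replicate 2's peaks had a q of 0.01 or less. These values describe, rank and filter peaks within a list only. Peak lists give no read counts, so sequencing depth per sample is unknown; a gene listed at 0% had no peak in that list, which a shallow library can also give, and the number and width of peaks move with depth.

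Gene bodies and exons were taken from the GENCODE release M21 annotation (GRCm38, the same coordinates as mm10), and known sequence and GC content from the GRCm38 FASTA. Results used protein-coding genes on chromosomes 1 to 19, X and Y, 21938 in number, and peaks on those chromosomes. Peaks within a list were merged to covered bases. A gene's value was the percent of bases from gene start to gene end inside peaks, as mean ± SD over the 2 replicates; a gene was called marked at 20% or more in each replicate. Overlapping genes share bases and so share values, and 4754 genes overlap another protein-coding gene. Position controls were 100 circular shifts of the peaks within each chromosome's known sequence. Profiles along genes used 20 equal bins for marked genes of at least 5 kb. Exon and intron coverage left out the first exon and intron of each gene and summed bases over all genes.

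The 30 gene lists were fixed before the data were examined, and all 2589 symbols in them were found in the annotation (5 families were taken by symbol pattern). Each list's median percent covered was ranked among 10000 random lists drawn within 20 gene length bins; a list was above chance at percentile 95 or higher and below at 5 or lower in each replicate. These percentiles describe the 2 libraries and are not p-values, since genes are not replicates. The number of marked members was compared with the same random lists as an addition made after the data were seen. The rule for named genes, also fixed beforehand, took a set of 24 facial, epithelial and chromatin genes whatever their values, in each list with any marked member the 2 highest and the lowest member by mean percent covered, the genes in the 5 longest domains, and the 5 genes of at least 5 kb with the largest replicate difference each way. Other genes are said to be picked after their values were seen.

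Gene calls were tested on simulated peaks laid over genes overlapping no other. Of 160 simulated genes at or above the limit 160 were called marked, with 0 other calls among such genes. The simulated shares were the same in both replicates, without noise and away from the limit. This outcome therefore checks the counting of covered bases only. The list comparison was tested on 200 random lists from all 21938 genes. It used the real coverage of both replicates and fewer draws than the main comparison. Of these lists 8 were counted above chance and 0 below by the median, and 9 above and 6 below by the number of marked members. Alternatives were a q of 0.01 or less, the same number of peaks (160417, the best by p of each list), the best 50000 peaks, limits of 10% and 40% for a marked gene, the replicated and pooled lists, each replicate alone, genes of at least 5 kb, genes overlapping no other, an overlap of 50% of the peak, and random lists matched on exon number too. No comparison between groups was possible and no p-value was computed. Peaks outside the assembled chromosomes were left out. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.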

Results

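H3K36me3, a histone mark laid down over the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the facial prominences of mouse embryos at embryonic day 10.5. The facial prominences are the buds of neural crest mesenchyme, covered by ectoderm, that form the face. The series held 1 group of 2 biological replicates. Replicate 1 was a pool of 69 embryos and replicate 2 a pool of 51 embryos, with both sexes mixed per the labels, so values describe tissue averaged over many embryos. The deposited files were peak lists on mouse build mm10. Replicate 1 held 294347 peaks covering 148.4 Mb and replicate 2 held 160417 peaks covering 154.9 Mb, which was 5.60% and 5.85% of the known sequence of the chromosomes. Read numbers were not part of these lists, so the depth behind each peak is unknown and no interval that needs depth is given. With a single group and no other tissue, stage or mark, the comparisons were replicate against replicate, gene group against length-matched genes, and gene part against gene part. Values for genes are the percent of the annotated gene body inside peaks, as mean ± SD over the 2 replicates (n = 2) throughout.

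The first question was which genes carried the mark in this tissue. Of 21938 protein-coding genes, 7615 (34.7%) had at least 20% of their body inside peaks in each replicate and are called marked here. Another 9755 genes (44.5%) had no covered base in either replicate. Replicate 1 alone gave 7800 such genes and replicate 2 alone 7848. Among the 30 gene lists fixed before the data were examined, 13 lay above length-matched chance in both replicates, which means a median at or above percentile 95 of 10000 random lists of equal size and gene length. By the same rule 0 lists lay below chance. The rule had little power on that side, because many random lists also had a median near 0: a simulated list of 25 genes with no coverage reached percentile 29.8 only. A second comparison, of the number of marked members, was therefore added after the data were seen; it put 12 lists above, 13 below and 5 between (chance limits of 5% on each side, tested once over the 2 replicates).

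**Figure D1:**
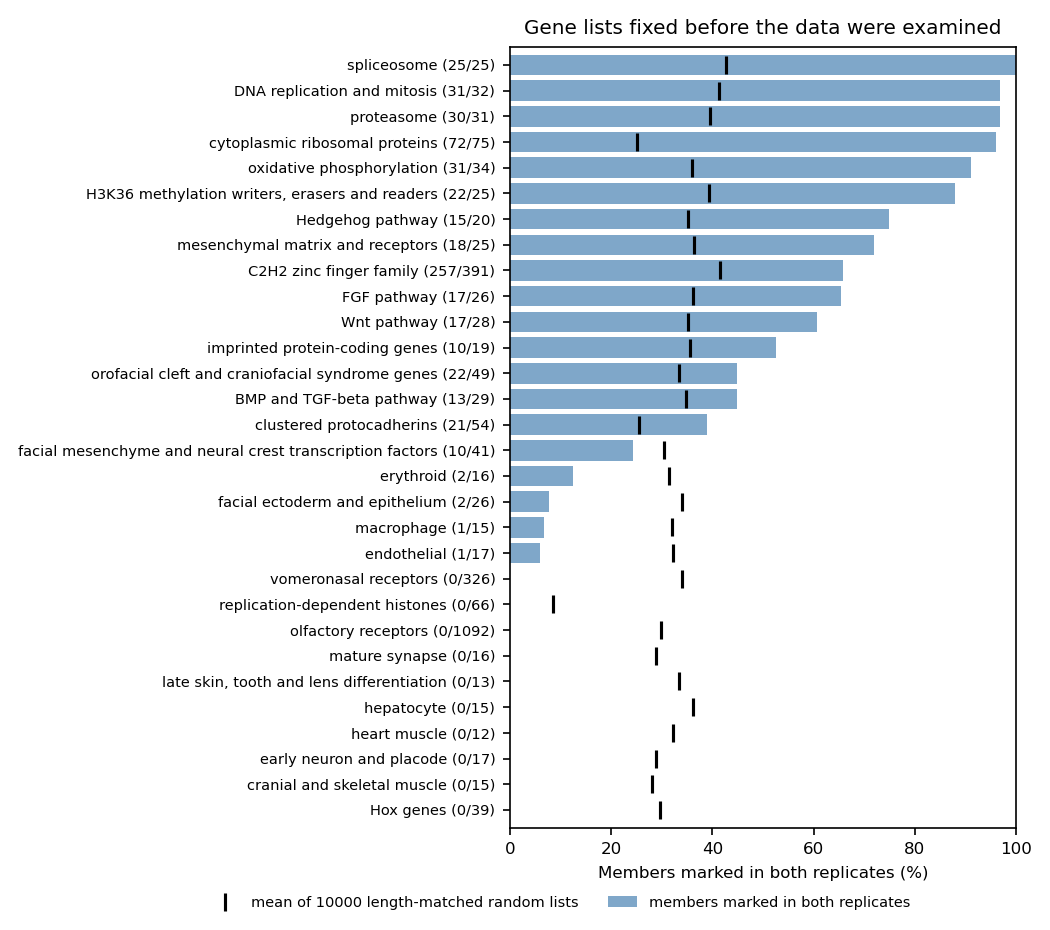
Percent of each list's members marked in both replicates (bars; marked and total members in parentheses) and the mean percent in 10000 random lists matched on gene length (black ticks). The spliceosome list reached 25 of 25 members, while Hox genes stood at 0 of 39.

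Genes of basic cell machinery were marked almost throughout. All 25 spliceosome genes were marked, led by Sf3b3 at 95.3% ± 1.29 and Sf3a1 at 94.3% ± 0.551, with Prpf6 lowest at 59.3% ± 1.37. The DNA replication and mitosis list had 31 of 32 members marked, with Top2a, the topoisomerase that untangles replicated DNA, at 94.7% ± 0.905 and Mcm5, a subunit of the replicative helicase, at 93.4% ± 3.47. Its unmarked member was the X-linked Pola1 at 6.36% ± 0.633. Proteasome genes were marked in 30 of 31 cases (Psmc6 88.9% ± 3.88, Psmc4 88.4% ± 0.935), the exception being Psmd14 at 11.4% ± 1.16. Cytoplasmic ribosomal protein genes were marked in 72 of 75 cases, with Rps15a at 91.3% ± 2.16, Rps28 at 83.6% ± 1.55 and Rpl36 lowest at 8.64% ± 12.2. Rps28 overlaps Kank3, which was itself covered over 39.1% of its body. Oxidative phosphorylation genes were marked in 31 of 34 cases, from Ndufa10 at 86.9% ± 2.64 and Uqcrc2 at 86.7% ± 3.91 down to the X-linked Ndufa1 at 0% in both replicates. The medians of these 5 lists all stood at percentile 100 of the random lists.

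Mesenchymal matrix and receptor genes were marked in 18 of 25 cases, against a mean of 9.11 in random lists, and their median of 54.1% lay at percentile 100. Fn1, which encodes fibronectin, had the highest coverage at 94.2% ± 1.34. Col2a1, the fibrillar collagen of cartilage, followed at 80.7% ± 1.31, and Pdgfra, a receptor of facial mesenchyme (chromosome 5, 75152292 to 75198215), at 79.5% ± 1.65. Col1a1, the main chain of type I collagen, averaged 55.0% ± 18.1, the widest spread between replicates in this list. Tnc, which encodes tenascin C, was lowest at 0.0963% ± 0.136.

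**Figure D2:**
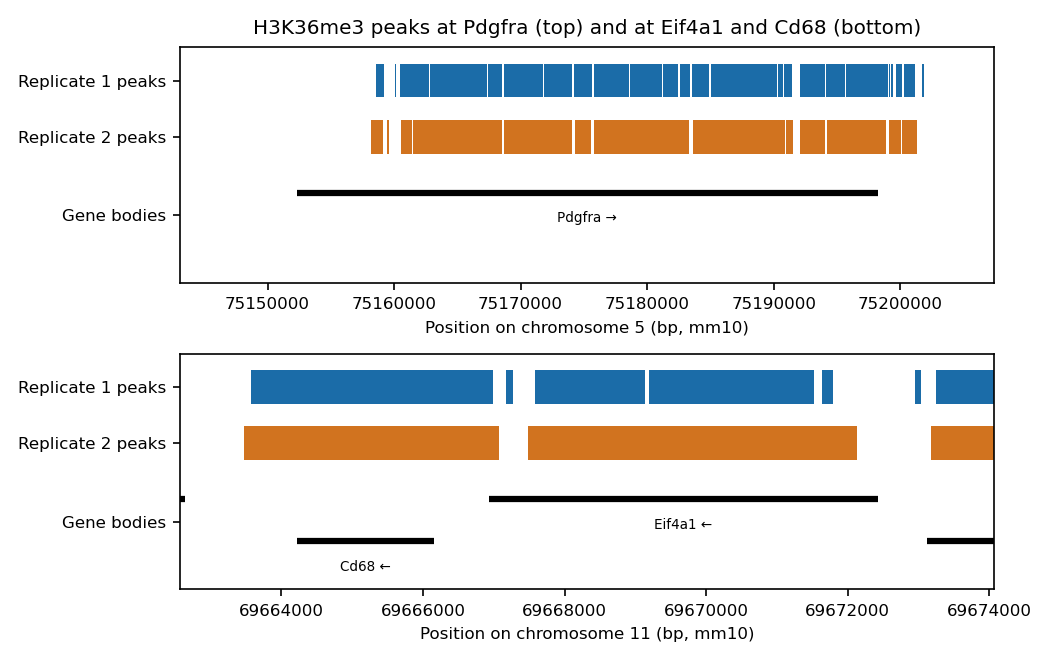
Peaks of each replicate (coloured blocks) and protein-coding gene bodies (black bars, arrows give the strand) around Pdgfra on chromosome 5 (top) and around Cd68 and Eif4a1 on chromosome 11 (bottom); the horizontal axes are mm10 positions in bp. Peaks filled 79.5% of Pdgfra on average, and 100% of Cd68, which lies 0.782 kb beyond the end of Eif4a1 on the same strand.

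The transcription factors that define facial mesenchyme and neural crest were covered over a smaller part of their bodies. Of 41 members, 10 were marked, against 12.5 on average in random lists, and the median of 9.28% lay at percentile 94.6, between the limits. Snai1 was highest at 80.1% ± 6.73. Alx4 followed at 48.2% ± 11.3 and overlaps Ext2, itself covered at 27.8%. Prrx1, a limb and face mesenchyme factor, stood at 44.4% ± 7.21, the cartilage regulator Sox9 at 33.6% ± 4.93 and Msx1 at 27.7% ± 1.78. Dlx5 missed the 20% limit at 19.6% ± 0.710. Other factors with known roles in the face had low coverage, with Twist1 at 8.80% ± 12.4, Barx1 at 8.02% ± 3.81, Alx1 at 3.55% ± 3.05, Pax3 at 3.05% ± 3.26 and Tfap2a at 2.96% ± 0.218. Sox10, Hand2 and Tfap2b had 0% in both replicates. Twist1 stood at 17.6% in replicate 1 and 0% in replicate 2. The bodies of Twist1 (2.16 kb), Barx1 (3.51 kb) and Hand2 (3.65 kb) are short, while Alx1 (31.5 kb), Pax3 (95.9 kb) and Tfap2a (23.1 kb) are longer. Whether length or exon number lowers such values was not tested for single genes. The number of marked members moved with the peak list used. It was 6 with the same number of peaks in both replicates, 1 with the best 50000 peaks of each and 17 with the pooled list. The list's median, though not its number of marked members, was also compared with random lists matched on exon number as well as length, where it was above chance in both replicates (percentile 99.4 in the lower replicate), as it was among genes overlapping no other (98.6).

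In the facial ectoderm list 2 of 26 members were marked. Its median of 0.836% lay at percentile 53.1, between the limits, whereas by the number of marked members, the comparison added later, 23 of 10000 random lists held as few. Tfap2c was covered at 21.1% ± 5.05 on average but under 20% in replicate 1, and Bmp4 at 12.02% ± 1.32 (both picked after their values were seen). Irf6, a clefting gene of the ectoderm, was covered at 1.58% ± 1.37, the epithelial cadherin gene Cdh1 at 1.14% ± 1.13, Shh at 0.536% ± 0.758 and the epidermal regulator Trp63 at 0.0794% ± 0.0363, while Fgf8 and Grhl1 had 0% in both replicates. The marked members were Esrp2 at 54.6% ± 0.701, which overlaps Nfatc3 (43.7% covered), and Krt18 at 37.5% ± 1.89. Krt18 lost its call with the same number of peaks, which left 1 marked member. Both lost theirs with the best 50000 peaks, which left 0.

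Gene lists named for other cell types, whether or not the dissected tissue could hold them, had few marked members. The endothelial list had 1 of 17 members marked, Fli1 at 45.7% ± 6.81, a call lost with the best 50000 peaks. Eng, a co-receptor of endothelial cells, had 7.99% ± 0.886 and overlaps Fpgs (41.5% covered), and Emcn had 0%. The erythroid list had 2 of 16 members marked, namely Tfrc, the transferrin receptor gene, at 75.3% ± 4.72, and Alas2 at 23.8% ± 1.64, which overlaps Apex2; Spta1 had 0%. That count was matched or undercut by 652 of 10000 random lists, so this list lay between the limits. Alas2 lost its call with a q of 0.01 or less, with the same number of peaks and with the best 50000 peaks, which each left 1 marked member. In the macrophage list 1 of 15 members was marked. This was Cd68, at 100% in both replicates, whose 1.94 kb body begins 0.782 kb beyond the end of Eif4a1 (81.7% ± 7.49) on the same strand. Cx3cr1, at 19.6% ± 0.266, has an annotated body of 168.3 kb that spans 5 other genes, among them Wdr48 at 73.2%, and Adgre1 had 0%. Marked members numbered 0 of 17 for early neurons and placodes, 0 of 15 for skeletal muscle, 0 of 16 for mature synapses, 0 of 15 for hepatocytes, 0 of 12 for heart muscle and 0 of 13 for late skin, tooth and lens genes. By number of marked members, each of the lists in this paragraph except the erythroid list was below length-matched chance.

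Of 4 signalling pathways active in facial outgrowth, Hedgehog, Wnt and FGF lay above length-matched chance. Random lists came from all protein-coding genes, 44.5% of which had no covered base. A list can therefore lie above them without being particular to facial signalling. The Hedgehog list had 15 of 20 members marked (percentile 99.9), with the receptor gene Ptch1 at 74.9% ± 2.94 and the ciliary gene Ift172 at 71.7% ± 0.568, whereas Hhip had 0.284% ± 0.272. The Wnt list had 17 of 28 members marked (percentile 99.4), among them the kinase gene Csnk1a1 at 80.6% ± 1.79 and Dvl3 at 80.1% ± 2.06, with the secreted ligand gene Rspo3 at 0.0527% ± 0.0746. The FGF list had 17 of 26 members marked (percentile 98.1), led by the kinase genes Mapk3 at 62.5% ± 1.43 and Map2k2 at 60.8% ± 1.69, while Fgf3 had 0%. Its other ligand genes, Fgf8, Fgf9, Fgf10, Fgf15 and Fgf17, were unmarked, with Fgf9 highest at 0.985% ± 0.371. The receptor genes Fgfr1 (49.1% ± 0.0934) and Fgfr3 (50.5% ± 1.13) were marked, and Fgfr2 (12.5% ± 0.861) and Fgfr4 (0.264% ± 0.373) were not. The body annotated for Fgfr2 is 2960.9 kb long and overlaps other gene sequence. Its value is a share of that whole span and does not show how far the receptor gene itself was covered. These ligand and receptor genes were picked after their values were seen. With the best 50000 peaks the marked members fell to 10 for Wnt and 8 for FGF. The BMP and TGF-beta list had 13 of 29 members marked, with Smad5 at 66.4% ± 3.80, Acvr2b at 58.1% ± 5.14 and Bmp2 at 0%; it passed the limit in replicate 1 (percentile 98.3) and not in replicate 2 (percentile 92.5), and in both among genes overlapping no other (99.8 in the lower replicate) and with matching on exon number (97.8). The replicated list (95.6) and the pooled list (97.3) also put it above. By number it lay between the limits, since 1638 of 10000 random lists held as many marked members.

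Of 49 orofacial cleft and craniofacial syndrome genes, 22 were marked and the median of 18.01% lay at percentile 98.5, above chance in both replicates. The number of marked members lay between the limits, since 528 of 10000 random lists held as many. Tcof1, mutated in Treacher Collins syndrome, was highest at 90.3% ± 1.46 and Kmt2d, mutated in Kabuki syndrome, followed at 89.8% ± 1.35. Tbx22, mutated in X-linked cleft palate, had 0% in both replicates.

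Genes for the H3K36 methylation machinery were themselves marked in 22 of 25 cases (percentile 100). Setd2, the enzyme that places trimethylation on H3K36, was covered at 77.2% ± 4.37 and the dimethyltransferase gene Nsd1 at 84.9% ± 4.03. The reader gene Glyr1 at 92.4% ± 0.814 and the demethylase gene Kdm4a at 92.1% ± 0.0361 were the highest, and Phf19 the lowest at 1.19% ± 1.68. Imprinted protein-coding genes were marked in 10 of 19 cases (percentile 96.4), with Nnat at 86.0% ± 6.04 inside Blcap (54.0% covered), Igf2r at 75.1% ± 3.06 and Ndn at 0%. By number the list lay between the limits, since 876 of 10000 random lists held as many marked members. Its median fell below the upper limit with the same number of peaks (percentile 87.7 in the lower replicate), with the best 50000 peaks (86.4), among genes overlapping no other (86.8) and with matching on exon number (91.0).

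Large gene families differed sharply. C2H2 zinc finger genes were marked in 257 of 391 cases, against 162.2 on average in random lists, with Zfp869 at 98.95% ± 1.48, Zfp2 at 91.9% ± 1.35 and Zfp804b at 0%. These genes were taken by symbol (Zfp followed by a number) and not by protein domain, so the list only approximates the family. Clustered protocadherins were marked in 21 of 54 cases, and all 21 were genes of the gamma cluster, where Pcdhgc4 had 61.1% ± 1.63 and Pcdhgc5 59.4% ± 2.47. Gamma genes share one 3' end, so their bodies overlap and are not separate observations. This list is among the 12 above chance by number (179 of 10000 random lists held as many), a call that rests on this single locus, while its median of 0% lay at percentile 4.56 and between the limits in each replicate. The alpha cluster had 0 of 11 listed members marked, Pcdha1 included at 0%, and the beta cluster 0 of 22. Listed alpha genes overlap as well and are not separate observations, and the symbol pattern left out Pcdhac1 and Pcdhac2. Hox genes were marked in 0 of 39 cases, Hoxa2 included at 0%, which 0 of 10000 random lists matched. Hox genes lie in clusters on chromosomes 2, 6, 11 and 15, and 12 of them overlap another gene. They are not separate observations, whereas random lists were drawn gene by gene. Replication-dependent histone genes were marked in 0 of 66 cases, olfactory receptors in 0 of 1092 and vomeronasal receptors in 0 of 326.

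Peaks lay inside genes. Of all peak bases, 94.2% ± 0.0461 fell in protein-coding gene bodies, which make up 39.3% of the known sequence; after 100 circular shifts of the peaks along their chromosomes the share was 41.6% on average for replicate 1 and 41.7% for replicate 2, and at most 44.1%. Along 6816 marked genes of at least 5 kb, the covered share rose from 4.77% ± 0.437 in the first of 20 bins to 75.9% ± 2.22 in bin 18, and was 68.4% ± 2.47 in the last. The last 5 bins exceeded the first 5 by 46.4 percentage points ± 0.454, far more than the spread between replicates. Bases were summed over 7239 marked genes of at least 3 exons, with the first exon and intron left out. Exons were covered at 73.6% ± 2.24 and introns at 54.5% ± 2.20. The exon excess was 19.1 points in replicate 1 and 19.2 points in replicate 2. Exons and introns were not compared gene by gene or at like positions. The excess is therefore not separated from differences between genes or from the rise along genes.

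**Figure D3:**
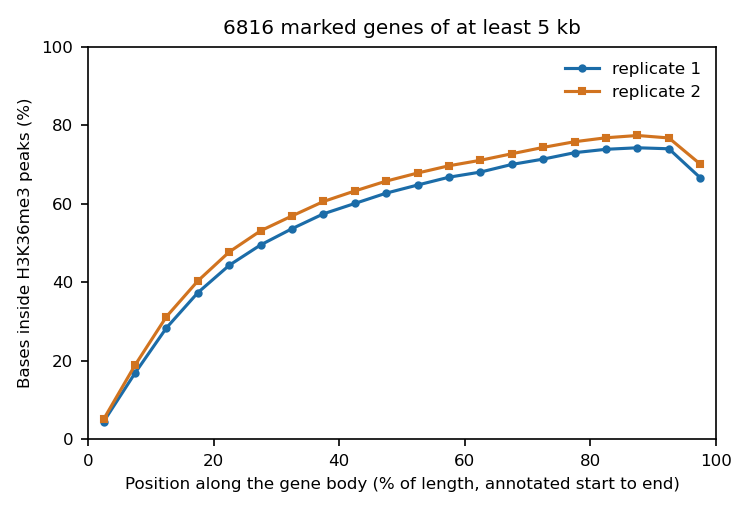
Percent of bases inside H3K36me3 peaks in 20 equal bins from the annotated start to the annotated end of 6816 marked genes of at least 5 kb, per replicate. Coverage rose from 4.47% and 5.08% in the first bin to 74.3% and 77.4% in bin 18 in replicates 1 and 2.

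The longest domains of the deposited replicated list, after merging peaks within 2 kb, ran over single transcription units or neighbours. The longest spanned 167.8 kb of chromosome 11 (23328836 to 23496657) over Usp34, a deubiquitinase gene (62.0% ± 5.58), and Ahsa2 (84.8% ± 2.80). The next covered 157.8 kb of chromosome 11 (62283195 to 62440997) over the co-repressor gene Ncor1 (71.6% ± 6.32) and Ttc19 (62.8% ± 3.04). A domain of 144.8 kb lay over the translation factor gene Eif4g3 on chromosome 4 (80.1% ± 4.24), one of 137.0 kb over Zfp827 on chromosome 8 (63.9% ± 1.03) and one of 135.5 kb over Zfp462 on chromosome 4 (79.5% ± 2.68).

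Genes on the X chromosome were marked less often than autosomal genes. On X, 130 of 948 protein-coding genes were marked (13.7%), against 7485 of 20807 on the autosomes (35.97%), where single chromosomes ranged from 27.3% on chromosome 14 to 44.7% on chromosome 8. Replicates taken alone gave 14.1% and 15.1% for X, and 36.8% and 37.0% for autosomes. The Y chromosome had 0 of 183 genes marked. Both pools mixed the sexes, and these values were not adjusted for the copy number of X and Y.

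The replicates were close to each other at the level of genes. Percent covered correlated across all 21938 genes with a Pearson r of 0.993 and a Spearman rho of 0.977. Genes are not independent replicates, and 9755 of them had no covered base in either list. Across marked genes alone the Pearson r was 0.971, and these genes differed by a median of 3.57 percentage points. In bases, the shared part was 69.7% of the union of both lists, against 3.36% on average and at most 3.99% in 100 circular shifts of replicate 2. Of replicate 1's peaks, 70.6% touched a peak of replicate 2 by at least 1 base, and 85.4% of replicate 2's peaks touched a peak of replicate 1. Replicate 1 had 1.83 times as many peaks but 0.958 times the covered bases, with a median peak width of 218 bp against 434 bp.

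**Figure D4:**
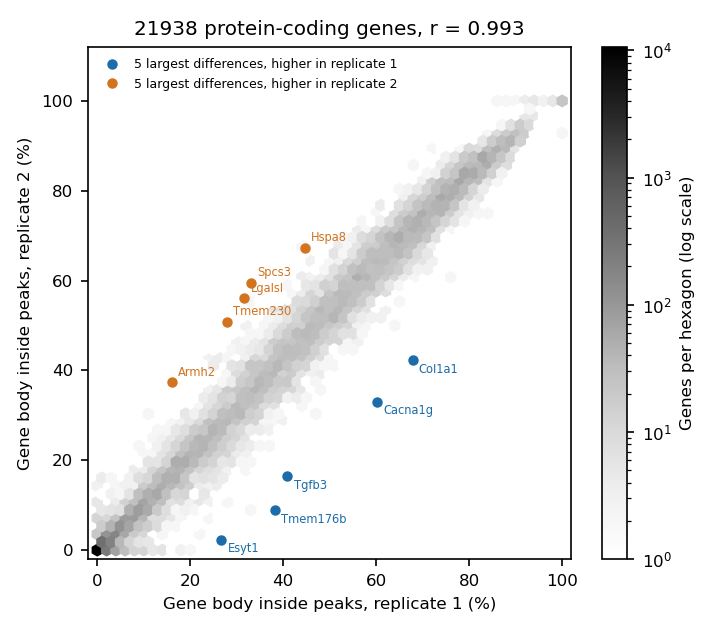
Percent of each protein-coding gene body inside peaks in replicate 1 (horizontal axis) and replicate 2 (vertical axis); shading gives the number of genes per hexagon on a log scale. Coloured points are the 5 genes of at least 5 kb with the largest difference in each direction, such as Tmem176b (38.2% and 8.86%) and Spcs3 (33.1% and 59.6%).

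Only 16 genes had at least 20% covered in 1 replicate and under 5% in the other, 7 of them in replicate 1 and 9 in replicate 2. Among these were the collagen VI genes Col6a1 (24.3% in replicate 1 and 1.53% in replicate 2) and Col6a2 (21.3% and 4.24%), picked here after their values were seen. Among genes of at least 5 kb, the largest differences towards replicate 1 were those of Tmem176b, Cacna1g, Col1a1, Tgfb3 and Esyt1, from 29.4 down to 24.3 percentage points. Towards replicate 2 they were those of Spcs3, Lgalsl, Tmem230, Hspa8 and Armh2, for which replicate 1 minus replicate 2 ran from -26.5 to -21.5 points. With 1 sample on each side, none of these differences has a test. The count was 49 genes with the same number of peaks, 197 with the best 50000 peaks and 3 among genes of at least 5 kb.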

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

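Both replicates held peaks outside the assembled chromosomes, on sequences that no comparison above used and for which the series has no control sample here. They are listed because their numbers exceed the 3 that a count of 0 would allow, a comparison without any control count. Replicate 1 had 26 such peaks on 4 sequences, 19 of them on a single sequence, and replicate 2 had 9 on 3 sequences, 6 of them on a single sequence, so the peaks are not independent counts. They covered 10.9 kb and 9.19 kb. Their median enrichment in the authors' lists was 3.04 in replicate 1 and 3.10 in replicate 2, against 3.55 and 3.32 for peaks on the chromosomes. No explanation for them was tested.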

How the results depend on the processing

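Merging peaks within 2 kb, leaving out the last exon, comparing lists by their number of marked members and leaving out receptor families were chosen after the data were seen; the other settings were fixed before. No paired analysis was possible because the series has a single group. The gradient, the exon excess and the X deficit kept their direction under every setting tried for them. The order of the replicates did not hold: replicate 2's peaks overlapped more often as deposited and replicate 1's with equal numbers of peaks, and genes covered in 1 replicate alone were more numerous in replicate 2 among all genes and in replicate 1 among those of at least 5 kb. The values that follow moved by more than the SD of the 2 replicates, the binomial interval of an overlap or 1.5 times a count, and the cause was not tested for any of them. With a q of 0.01 or less the shared bases were 70.1% of the union, 71.7% of replicate 1's and 83.8% of replicate 2's peaks overlapped, 94.25% of peak bases lay in gene bodies, the gradient was 46.9 points, the exon excess 18.7 points and 35.2% of autosomal genes were marked. With the same number of peaks these were 68.7%, 87.8%, 64.4%, 94.4%, 48.2 points, 17.4 points and 33.1%, with 10.1% of X genes marked and 49 genes in 1 replicate alone, 1 in replicate 1 and 48 in replicate 2. With the best 50000 peaks the first 6 were 67.5%, 91.4%, 66.4%, 95.01%, 52.2 points and 16.1 points, with 197 genes in 1 replicate alone, 12 in replicate 1 and 185 in replicate 2. Requiring 50% of a peak gave overlaps of 63.6% and 67.5%, and merging within 2 kb gave 80.7% shared bases and overlaps of 65.4% and 85.3%. The replicated list gave 94.23% of peak bases in bodies, 47.2 and 20.3 points, and 15.7% of X and 37.6% of autosomal genes; the pooled list gave 93.9%, 45.6 and 20.4 points, and 1 list below chance. Leaving out a replicate in turn, given as ranges in which at least 1 end moved, gave a gradient of 45.8 to 46.4 points, an exon excess of 19.4 to 19.7 points, 14.1% to 15.1% of X and 36.8% to 37.0% of autosomal genes, and 0 to 1 lists below chance. Leaving out the last exon gave an excess of 21.2 points. A limit of 10% of the body gave 19.9% of X and 41.6% of autosomal genes, and 40% gave 6.86% and 25.996%. Without receptor families 38.6% of autosomal genes were marked. Genes of at least 5 kb left 3 genes in 1 replicate alone, 3 in replicate 1 and 0 in replicate 2. Matching on exon number put 1 list below chance, the mature synapse list, and the number of marked members put 13 there. Marked genes numbered 5304 to 8837 over all settings, within 1.5 times 7615, and lists above chance 12 to 14. Of the 97 named genes 58 were marked, and the best 50000 peaks lost 13 of them, Prrx1, Alx4, Msx1, Sox9 and Col1a1 included. The unknown read depth limits what a missing peak can show.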

Other observations

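The tests of short and single-exon bodies for histone genes and of GC content and length for matrix genes, and the leaving out of single matrix genes, were written after related values had been seen; the others were written before theirs. Several noncoding genes outside protein-coding bodies carried the mark. In the imprinted Meg3 cluster on chromosome 12, Meg3 stood at 77.2% ± 1.77, Rian at 50.2% ± 3.38 and Mirg at 83.3% ± 5.01 (SD, n = 2 for all genes here). The snoRNA host Snhg1 had 76.5% ± 5.12 and Malat1 69.7% ± 3.50, whereas its neighbour Neat1 had 0% in both replicates. These genes were picked after their values were seen. Of 5358 long intergenic RNA genes outside protein-coding bodies, 73 (1.36%) were marked.

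Zinc finger genes were frequent under the strongest peaks. Of the best 100 peaks by p, 39 in replicate 1 and 34 in replicate 2 lay over C2H2 zinc finger genes, taken by symbol. The shares were 10.6% and 10.2% of the best 1000 peaks and 1.91% and 1.96% of all peaks. The mark also ran past gene ends: the 5 kb downstream of marked genes that overlap no other gene were covered at 25.7% ± 0.672, and the 5 kb upstream at 1.33% ± 0.0617 (windows free of other genes; 2978 and 3366 genes). Among genes of 20 to 50 kb, 22.1% of those with 2 to 3 exons were marked and 64.2% of those with 16 exons or more.

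Fewer X-linked genes were marked. Gene content as the whole explanation was put against 40 hand-written pairs of an X-linked and an autosomal gene of like function, for which equal coverage would leave the X-linked member lower in 27 or more pairs in under 5% of draws. The X-linked member was lower in 31, with medians of 47.1% and 68.2%. Lengths lay within 1.5 times in 18 pairs, and the X-linked member was lower in 16 of these. By the limit for a marked gene, 30 X-linked and 37 autosomal members were marked. Pairs come from the same 2 libraries and are not independent draws, so the limit of 27 is a guide only. For these pairs the lower coverage argues against gene content as the whole cause. Of pairs picked after their values were seen, G6pdx had 7.72% against 89.3% for Pgd. The other way, Hcfc1 had 85.6% against 31.7% for Hcfc2. The median enrichment of peaks over 304 X-linked genes was 3.96 in replicate 1 and 3.77 in replicate 2, against 5.42 and 5.08 in autosomal genes of like length, at percentile 0 of 10000 random lists in both replicates. Enrichment and coverage are readings of the same signal, so this describes a weaker signal over X-linked genes without giving its cause. Gene content as a part of the cause, the copy number of X in pools of both sexes and any biological explanation were not tested.

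None of the 66 replication-dependent histone genes was marked, although 31 of 32 replication and mitosis genes were. As few marked genes were held by 24 of 10000 length-matched random lists and by 221 of 10000 lists of single-exon genes near in length. The histone genes lie mostly in clusters on chromosomes 13 and 3 and are not separate observations. Random lists were drawn gene by gene, so these low counts cannot by themselves exclude short bodies or a single exon. Sequence shared between copies, which may keep reads from being placed, stays open: 9 histone genes had at least 90% of their 32-base words once in the genome, 0 of them marked, which is under the 10 genes asked for beforehand. No biological explanation was tested.

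Matrix genes leaned towards replicate 1 relative to matched genes, although only 9 of 22 were higher in replicate 1 itself. Coverage in replicate 1 minus replicate 2 rose with GC content (Spearman rho 0.344 across 6816 genes, which are not independent), and the matrix list's median of -0.806 points compared with -2.04 in random lists matched on GC content and length, at percentile 95.46. Leaving out single members took this to between 85.5 and 98.2, so GC content stays open. With the same number of peaks the matrix list stood at 98.97 (96.3 to 99.5), and the second matrix list named below at 94.505. That setting removed peaks from replicate 1 only, and it moved unrelated lists too. The spliceosome list rose from 38.68 to 98.735 and the DNA replication and mitosis list from 17.465 to 95.575. The Hedgehog list fell from 96.635 to 49.995. The setting therefore cannot separate peak number from other causes, and peak number stays open. A difference in developmental progress between the pools might show as early embryo genes towards replicate 2 and a second matrix list towards replicate 1: the former (15 genes, Sall4 among them) stood at percentile 0.01 with 0 of 15 higher in replicate 1, the latter at 90.1, short of the limit, so this stays open, and the design has no stage groups. Of 18 lists 7 lay at or past a limit of 5 or 95 in this comparison, C2H2 zinc finger genes at 100 and imprinted genes at 0 among them, so extreme percentiles were common.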
